A study of Mus musculus with 8 samples.

How the data were processed

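Total RNA from mouse hearts was labelled with biotin and hybridised to the Affymetrix Mouse Gene ST array, per the labels. There were 8 arrays in 4 groups of 2: WT sham, KO sham, WT MI and KO MI. Genotype and condition came from the labels, and replicate numbers from the sample titles. The deposited values are log2 expression values that the authors made with Affymetrix Expression Console and the RMA method, per the submitters' processing notes, which name no further steps. Versions are not given in the sources used here. The RMA method as commonly run includes quantile normalization, which makes the distributions of the arrays alike, so a shift shared by most genes would be reduced. Detection calls and scan dates were not used here.

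The table held 35556 probes. The platform annotation paired 21789 of them with 1 gene and 1621 with several, and did not list 12146, which are unnamed here. Of the probes with 1 gene, 21698 were matched by Entrez ID to a RefSeq gene table and 91 were not, and 0 symbols needed an update. One probe per gene was tested, the one with the highest mean over the 8 arrays, which mattered for 999 genes with more than 1 probe and left 19938 genes. There was no filter on low values. Apart from the RefSeq table (mouse assembly GRCm38.p6), the sources used here name no genome build, so no coordinates are given. That table served for names, for which genes neighbour Fbxo32 and for distances from it.

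Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. All 8 arrays entered 1 fit with 4 group means (4 residual degrees of freedom and 5.57 from the prior), with two-sided tests and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. The contrasts were MI against sham in WT and in KO, KO against WT in sham and in MI, and the difference of the MI responses. The KO effect averaged over conditions used condition as an additive term (5 residual degrees of freedom). With 2 arrays against 2 an exact two-sided permutation test cannot give a p under 0.333, so p-values come from the model. The number of arrays limits the precision.

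Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 33 lists within a contrast, with camera at an estimated correlation and with fry as alternatives. The lists covered leukocyte, resident macrophage, fibroblast, endothelial, smooth muscle, cardiomyocyte, atrial, adipose, mesothelial and erythrocyte markers, cytokines, NF-kB targets, matrix genes and proteases, stress and immediate early genes, metabolism, ubiquitin ligases, autophagy, proteasome, interferon, cell cycle, cell death, hypoxia, unfolded protein, heat shock, calcineurin and sex-linked genes, and genes next to Fbxo32. Groups, tests, lists, alternatives and the rule for naming genes were fixed in advance. That rule named Fbxo32, and up to 10 rises and 10 falls per contrast, the largest among genes past the threshold whose arrays did not overlap between groups (the threshold alone for the averaged effect). Where 0 genes passed it named the 3 with the smallest p in each direction. It added up to 4 members of each list with the smallest p. Clone, predicted and Riken names and receptor segments were counted but not named, which left out 183 changed genes in WT MI and 130 in KO MI. Alb and Car3 were singled out, and Sln, Myl7 and the genes nearest Fbxo32 given, after values had been seen.

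The alternatives were an intensity trend or a robust prior, array weights, removal of the lowest 33.3% of genes by mean level, the mean of a gene's probes, all probes, the 2 compared groups alone, cyclic loess, median centring, the replicate number as a block, a 2-fold minimum, removal of genes within 20 Mb of Fbxo32, and leaving out each array in turn, where a lone array is assumed to vary like the other groups. The joint removal of KO sham replicate 1 and WT MI replicate 2 was chosen after seeing the data, as was the use of all probes for the adjusted p of named genes, planned for counts only. The code was tested on simulated data for 19938 genes. For the KO effect in MI it called 8.96% of genes changed by 0.5 on the log2 scale, 65.7% of those changed by 1 and 98.5% of those changed by 2, with 8 false calls among 19718. For the difference of the responses it called 0, 32.8 and 84.8% in the same order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.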

Results

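Gene expression was measured in RNA from mouse hearts with the Affymetrix Mouse Gene ST array. Hearts came from wild-type (WT) mice and from mice lacking MAFbx (KO), the muscle ubiquitin ligase also called atrogin-1, which the gene Fbxo32 encodes. Mice of both genotypes had either a sham operation or a permanent ligation of the left coronary artery, which causes a myocardial infarction (MI), and RNA was taken 1 day after the ligation; the time after a sham operation is not given in the labels. The 4 groups were WT sham, KO sham, WT MI and KO MI, with 2 arrays in each. The title of the series names cardiac rupture after infarction as the subject of the study. The labels do not say whether the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. The deposited values were on a log2 scale for 35556 probes, with array medians between 5.004 and 5.253, and 19938 genes were tested. Infarcted and sham hearts separated along the first principal component, which held 73.9% of the variance. On it the sham arrays lay between -40.1 and -36.4, the WT MI arrays at 44.3 and 47.6, and the KO MI arrays at 31.4 and 32.5. On the second component, with 8.56% of the variance, KO sham replicate 1 (-21.2) and WT MI replicate 2 (-20.2) stood apart from the other array of their group (15.3 and 0.63), and the KO MI arrays lay at 16.2 and 8.64. The arrays of a group correlated across genes at r = 0.993 in WT sham, 0.993 in KO MI, 0.990 in WT MI and 0.981 in KO sham, where genes are not independent replicates.

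Fbxo32 was low in every KO array. Its mean log2 level was 8.78 ± 0.03 (SD, n = 2) in WT sham, 4.93 ± 0.35 (SD, n = 2) in KO sham, 8.28 ± 0.10 (SD, n = 2) in WT MI and 5.30 ± 0.23 (SD, n = 2) in KO MI. It was 14.4-fold lower in KO than in WT after sham surgery (log2 fold change -3.85, SE 0.18, limma adjusted p = 3.77e-05) and 7.9-fold lower after MI (log2 fold change -2.98, SE 0.18, adjusted p = 0.00041). With all probes tested in place of 1 per gene, its adjusted p after MI was 0.0523 (range over alternatives 8.03e-05 to 0.0523), and it passed in sham (adjusted p = 0.0101). Infarction left Fbxo32 short of the threshold in both genotypes, with a log2 fold change of -0.49 (SE 0.18, adjusted p = 0.0662) in WT and 0.37 (SE 0.18, adjusted p = 0.184) in KO. Without KO sham replicate 1 or without KO sham replicate 2 the fall in WT passed (adjusted p = 0.0253, range over alternatives 0.0207 to 0.247), and without KO sham replicate 2 the rise in KO did (adjusted p = 0.0355, range 0.0355 to 0.655). The part of the gene that was deleted is not given in the labels, so the level left in KO has no reference here.

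**Figure D1:**
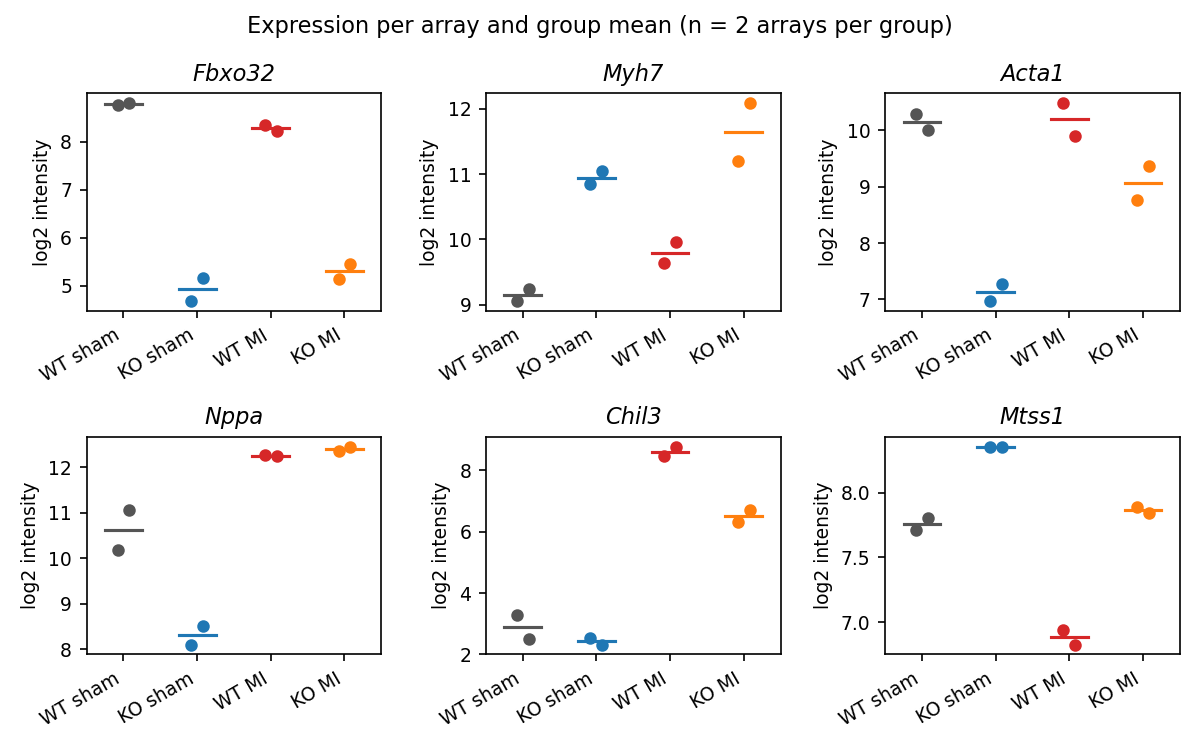
Points give the log2 intensity of 6 genes in each array, by group on the horizontal axis, and lines give the mean of the 2 arrays of a group. Fbxo32 lay near 5 in the KO arrays, Myh7 was higher and Acta1 lower in KO than in WT in both conditions, and Nppa was low in KO sham but near 12 in both MI groups. The vertical axes do not start at 0.

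The first comparison set WT hearts 1 day after infarction against WT sham hearts. Transcripts of neutrophils, the first leukocytes to enter injured tissue, were among the largest rises. S100a8, a subunit of the neutrophil protein calprotectin, rose 73.3-fold (log2 fold change 6.20, SE 0.32, adjusted p = 1.88e-06), and Cxcr2, the receptor that draws neutrophils along chemokine gradients, rose 72.4-fold. Lcn2 rose 69.1-fold, Slfn4 50.7-fold, Retnlg 38.9-fold and the decoy receptor of interleukin-1, Il1r2, 34.7-fold. Timp1, an inhibitor of matrix metalloproteinases, rose 55.2-fold (log2 fold change 5.79, SE 0.23, adjusted p = 6.98e-07). Chil3 and Arg1, which activated macrophages express, rose 52.3-fold and 37.9-fold, and the neutrophil chemokine Cxcl2 rose 50.7-fold. S100a8, Cxcr2, Retnlg, Il1r2, Chil3 and Cxcl2 read between 2.51 and 4.40 in the WT sham arrays, near the low end of the array (10th percentile of genes 3.045), so their folds and order are uncertain, and detection was not tested. In all, 5609 of 19938 genes changed at an adjusted p under 0.05, of which 2457 rose and 3152 fell, and 773 rises and 897 falls were at least 2-fold.

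The largest falls in WT hearts included Lgi1 (17.9-fold lower, adjusted p = 0.00019), the integrin subunit Itgb6 (12.1-fold lower), Mrgprh (9.07-fold lower), Ecm2 (7.92-fold lower), Inmt (7.80-fold lower), Stxbp4 (7.07-fold lower), Mfsd4b3-ps (6.89-fold lower) and the proprotein convertase Pcsk6 (6.82-fold lower). Alb, which encodes the liver protein albumin, fell by 6.01 on the log2 scale (SE 1.07, adjusted p = 0.0024), and Car3, a carbonic anhydrase abundant in fat and skeletal muscle, fell by 3.75 (SE 0.73, adjusted p = 0.00392). Both varied widely among sham arrays. Alb read 9.12 and 10.46 in the WT sham arrays, 10 and 5.56 in the KO sham arrays and between 3.64 and 3.90 in the 4 MI arrays. Lgi1 read 4.91 and 3.42 in the WT MI arrays, so the folds and order of falls whose lower side is near the low end of the array are uncertain too. This does not cover Pcsk6, which read 6.915 and 6.527 there, above the median gene (5.798). Other liver transcripts moved with Alb: of 15 liver genes listed after Alb was seen, 7 fell in WT MI. The mean of the 15 relative to WT sham was -1.38 in KO sham replicate 2 against 0.08 in KO sham replicate 1.

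Of 33 gene lists fixed before the data were examined, 14 shifted up and 7 down in WT MI by camera with its preset correlation. Among cytokines and chemokines 23 of 26 measured members rose and 0 fell, with a median log2 fold change of 2.27 (camera adjusted p = 1.63e-16). This list also passed with an estimated correlation (adjusted p = 0.0211). Ccl2, the chemokine that recruits monocytes, rose 20.4-fold, and Il1b, which encodes the inflammatory cytokine interleukin-1 beta, rose 15.1-fold. Adjusted over the list alone, 24 members rose. Of 21 neutrophil markers 18 rose (20 adjusted over the list alone), with a median of 4.08 (camera adjusted p = 1.63e-16, but adjusted p = 0.0734 with an estimated correlation). Of 23 monocyte and macrophage markers 13 rose, also when adjusted over the list alone, with a median of 1.79 (camera adjusted p = 2.04e-07, adjusted p = 0.246 with an estimated correlation), among them the integrin Itgam (23.0-fold) and the scavenger receptor Msr1 (9.63-fold).

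Matrix and stress genes followed. Of 25 matrix proteases and inhibitors 14 rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.84, including the urokinase receptor Plaur (16.2-fold) and the aggrecanase Adamts4 (12.9-fold), with a camera adjusted p of 8.37e-05 and an adjusted p = 0.237 with an estimated correlation. Of 9 fetal and wall stress genes 7 rose and 0 fell (8 adjusted over the list alone), with a median of 1.53 (camera adjusted p = 1.96e-06, adjusted p = 0.0734 with an estimated correlation). Tnfrsf12a, the receptor of the cytokine TWEAK, rose 5.99-fold, and the filamin Flnc 3.54-fold. Of 24 NF-kB pathway genes 17 rose and 2 fell, counts that held adjusted over the list alone (median 0.89, camera adjusted p = 1.96e-06, adjusted p = 0.0956 with an estimated correlation). Immediate early genes rose in 15 of 22 members and fell in 1 (15 and 2 adjusted over the list alone), including Ier3 (7.85-fold) and Fosl1 (6.84-fold), with a camera adjusted p of 1.96e-06 and an adjusted p = 0.245 with an estimated correlation. All 31 proteasome subunits lay above 0 and 14 of them rose (17 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 3.98e-06, adjusted p = 0.489 with an estimated correlation).

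Further upward shifts in WT MI covered the unfolded protein response (7 of 12 rose, among them the asparagine synthetase Asns, 4.06-fold), hypoxia response (9 of 19, among them the glucose transporter Slc2a1, 6.63-fold), heat shock genes (5 of 10, among them Hspb1, 5.81-fold), cell death (12 of 22, among them the inflammasome sensor Nlrp3, 5.76-fold from a sham level near the low end of the array), interferon-stimulated genes (6 of 17) and lymphocyte markers (3 of 16). None of these 6 passed with an estimated correlation, where the adjusted p values were 0.237, 0.174, 0.237, 0.175, 0.612 and 0.489 in the same order. Adjusted over the list alone, the counts of rises were 8, 10, 6, 14, 9 and 2. Among all 19938 genes tested 2457 rose. Over all genes 3 hypoxia response, 1 heat shock and 1 cell death gene fell, also adjusted over the list alone. Interferon-stimulated genes missed the threshold without WT MI replicate 1 (adjusted p = 0.386), heat shock genes likewise (adjusted p = 0.0531), and lymphocyte markers without WT sham replicate 1 (adjusted p = 0.09) or WT MI replicate 2 (adjusted p = 0.137), with low genes removed (0.117), with cyclic loess (0.125) or with an intensity trend (0.0579).

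Another 7 lists shifted down in WT MI by camera with its preset correlation, and none of them with an estimated one. The counts of members that fell stand beside 3152 falls among all 19938 genes. All 12 smooth muscle and pericyte markers lay below 0 and 8 fell, also adjusted over the list alone, with a median of -0.70, among them the smooth muscle myosin Myh11 (3.59-fold lower) and the potassium channel subunit Abcc9 (2.46-fold lower). Of 10 fibroblast markers 5 fell and 1 rose (median -0.53), including the matrix protein gene Dpt (3.18-fold lower). Of 23 cardiomyocyte contractile and calcium genes 8 fell and 1 rose (median -0.17), including the L-type calcium channel subunit Cacna1c (2.63-fold lower). Of 25 fatty acid oxidation genes 5 fell and 1 rose (median -0.27), including the regulators Ppara (2.67-fold lower) and Ppargc1a (2.501-fold lower). Of 30 oxidative phosphorylation genes 29 lay below 0 and 4 fell (median -0.19), and of 9 calcineurin and NFAT genes 5 fell and 1 rose (median -0.65). Of 4 sex-linked genes the Y-linked Kdm5d (2.16-fold lower) and Uty (3.11-fold lower) fell (median -0.94). Adjusted over the list alone, falls numbered 5 for fibroblast markers, 9 for cardiomyocyte genes, 5 for fatty acid oxidation, 2 for oxidative phosphorylation, 7 for calcineurin and NFAT genes and 2 for sex-linked genes. These 7 lists passed with the preset correlation, at camera adjusted p values between 0.000125 and 0.0459, and with an estimated one the adjusted p ranged from 0.174 for smooth muscle to 0.651 for fatty acid oxidation. Without WT MI replicate 2 the fibroblast markers missed the threshold (adjusted p = 0.0612). The sex-linked genes did so without WT sham replicate 2 (0.0542), either KO sham array (0.0662) or WT MI replicate 2 (0.0695), all adjusted p values. With low genes removed 13 lists shifted up and 2 down, and of these 7 the smooth muscle and oxidative phosphorylation lists stayed, while the others had adjusted p values between 0.0707 and 0.0836.

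Lists without a shift in WT MI also held genes that changed. Of 23 extracellular matrix genes 8 rose and 6 fell, and fibronectin (Fn1) rose 4.70-fold and tenascin C (Tnc) 25.5-fold, an uncertain fold since it read 3.89 and 4.155 in WT sham. Among resident macrophage markers F13a1 rose 2.60-fold while Folr2 was 2.49-fold lower, and the atrial markers held a rise of Nppa (3.12-fold) beside falls of Dkk3 and Myl4, the latter lost without WT sham replicate 2 (adjusted p = 0.141), WT MI replicate 1 (adjusted p = 0.0633) or WT MI replicate 2 (adjusted p = 0.11, range over alternatives 0.00331 to 0.141). Glycolysis genes rose in 6 of 16 members and fell in 3. The extracellular matrix list passed without WT sham replicate 2 (adjusted p = 0.0209) or WT MI replicate 2 (adjusted p = 0.00955). Atrial markers passed, below 0, without WT sham replicate 1 (adjusted p = 0.0229). With WT sham replicate 1 or 2 left out, the count of changed genes in WT MI was 3457 or 3462, against 5609 with all arrays. Centring each array on its median put 33.6% of the changed genes on the rising side, against 43.8% in the deposited values.

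The second comparison asked the same of KO hearts, where 4142 genes changed, 2098 up and 2044 down, with 676 rises and 350 falls of at least 2-fold. Timp1 rose 60.7-fold (log2 fold change 5.92, SE 0.23, adjusted p = 1.12e-06), Lcn2 53.8-fold, Cxcr2 32.7-fold, S100a8 31.4-fold, Arg1 29.9-fold, Slfn4 28.4-fold and S100a9, the partner of S100a8, 20.2-fold. Sprr1a rose 24.7-fold, Tnc 23.1-fold and Nmrk2, a muscle kinase that makes NAD precursors, 20.4-fold. Cxcr2 and S100a8 read between 3.09 and 4.14 in the KO sham arrays, so their folds are uncertain as well. The largest falls included Alb (16.6-fold lower, adjusted p = 0.0242), Mrgprh (8.002-fold lower), Lgi1 (5.61-fold lower), Hmcn1 (4.63-fold lower), the enkephalin precursor Penk (4.62-fold lower), Lgals4 (4.61-fold lower), Itgb6 (4.56-fold lower), Pkd2l2 (4.48-fold lower), the apelin receptor Aplnr (4.17-fold lower) and the potassium channel subunit Kcnv2 (4.17-fold lower). The fall of Alb rested on a KO sham group with an SD of 3.14 on the log2 scale, and it was lost without KO MI replicate 1 (adjusted p = 0.115) or 2 (adjusted p = 0.105, range over alternatives 0.000151 to 0.12).

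In KO hearts 15 lists shifted up and 2 down. Cytokines and chemokines (21 of 26 rose, 22 adjusted over the list alone, median 1.75, camera adjusted p = 9.83e-19) also passed with an estimated correlation (adjusted p = 0.0164). So did fetal and wall stress genes (8 of 9 rose, 9 adjusted over the list alone, median 1.86, camera adjusted p = 1.43e-10, adjusted p = 0.0363 with an estimated correlation). In that list the natriuretic peptide genes Nppa and Nppb, released by stretched heart muscle, rose 17.0-fold and 11.4-fold. Nppa rose from a lower sham level in KO (8.106 and 8.524) than in WT (10.19 and 11.06). Neutrophil markers rose in 14 of 21 members (16 adjusted over the list alone, where 1 fell, median 2.77, camera adjusted p = 2.58e-14, adjusted p = 0.0579 with an estimated correlation), and monocyte and macrophage markers in 13 of 23 (13 adjusted over the list alone, median 1.71, camera adjusted p = 6.95e-10, adjusted p = 0.225 with an estimated correlation). Proteasome subunits rose in 20 of 31 members (26 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 1.81e-11, adjusted p = 0.355 with an estimated correlation). Extracellular matrix genes rose in 13 of 23 members and fell in 2 (14 and 3 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 0.00019, adjusted p = 0.513 with an estimated correlation). Glycolysis genes rose in 10 of 16 members and fell in 3 (11 and 3 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.000462, adjusted p = 0.373 with an estimated correlation), including Slc2a1 (6.01-fold) and the phosphofructokinase Pfkp (3.60-fold).

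The other upward shifts in KO MI were NF-kB pathway genes (16 of 24 rose), matrix proteases and inhibitors (14 of 25), immediate early genes (11 of 22), hypoxia response (11 of 19), unfolded protein response (9 of 12), heat shock genes (4 of 10), cell death (11 of 22) and interferon-stimulated genes (5 of 17). With an estimated correlation their adjusted p values were 0.0579, 0.225, 0.299, 0.0579, 0.216, 0.216, 0.216 and 0.607, all short of the threshold. Adjusted over the list alone, the counts of rises were 18, 14, 15, 14, 10, 6, 11 and 5. Over all genes 2 NF-kB pathway, 3 matrix protease, 1 immediate early, 2 hypoxia response and 1 cell death gene fell (3, 4, 2, 2 and 1 adjusted over the list alone). Smooth muscle and pericyte markers (4 of 12 fell, median -0.22) and fatty acid oxidation genes (4 of 25 fell, median -0.20) shifted down, at camera adjusted p values of 0.0297 and 0.0162, and with an estimated correlation at an adjusted p = 0.299 and an adjusted p = 0.762. Those counts of falls held adjusted over the list alone. The smooth muscle shift was lost without KO sham replicate 2 (adjusted p = 0.0674) or KO MI replicate 2 (adjusted p = 0.132) and with low genes removed (adjusted p = 0.0712), and the fatty acid oxidation shift without KO sham replicate 2 (adjusted p = 0.684) or KO MI replicate 1 (adjusted p = 0.139). Without KO MI replicate 1 or 2 the count of changed genes was 2305 or 2246, against 4142 with all arrays. Centring each array on its median put 62.3% of the changed genes on the rising side, against 50.7% in the deposited values.

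The responses of both genotypes, which share no array, correlated across genes at r = 0.875 and Spearman's rho = 0.749, where genes are not independent replicates. Of the genes changed in both, 3314 of 3315 moved in the same direction, and 68.4% of those 3315 had the larger change in WT. The test of the difference itself found 0 genes by limma at an adjusted p under 0.05, against 1637 at an unadjusted p under 0.05 where chance would give 997. The genes nearest the threshold were Snora31 (log2 difference -1.55, SE 0.17, adjusted p = 0.0773), Grk3 (-1.37, adjusted p = 0.161) and Sla (-1.42, adjusted p = 0.161) on the side of a lower response in KO. On the other side stood Cd59a (1.57, adjusted p = 0.161), Nppa (2.45, adjusted p = 0.161) and Fbxl22 (1.35, adjusted p = 0.171). For each of the latter, and for Grk3, the genotypes lay further apart in sham than in MI. Nppa read 10.19 and 11.06 in WT sham and 8.106 and 8.524 in KO sham. After MI it read 12.27 and 12.25 in WT and 12.36 and 12.45 in KO. As lists, neutrophil markers had a smaller rise in KO than in WT, with a median difference of -0.75 and 20 of 21 members below 0 (camera adjusted p = 1.03e-10), although the adjusted p was 0.226 with an estimated correlation. Centring each array on its median moved the median difference of all genes from 0.01 to 0.17, and the neutrophil median was then -0.59. An intensity trend in the prior gave 4 genes, cyclic loess scaling gave 1, and leaving out WT sham replicate 1 gave 3.

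**Figure D2:**
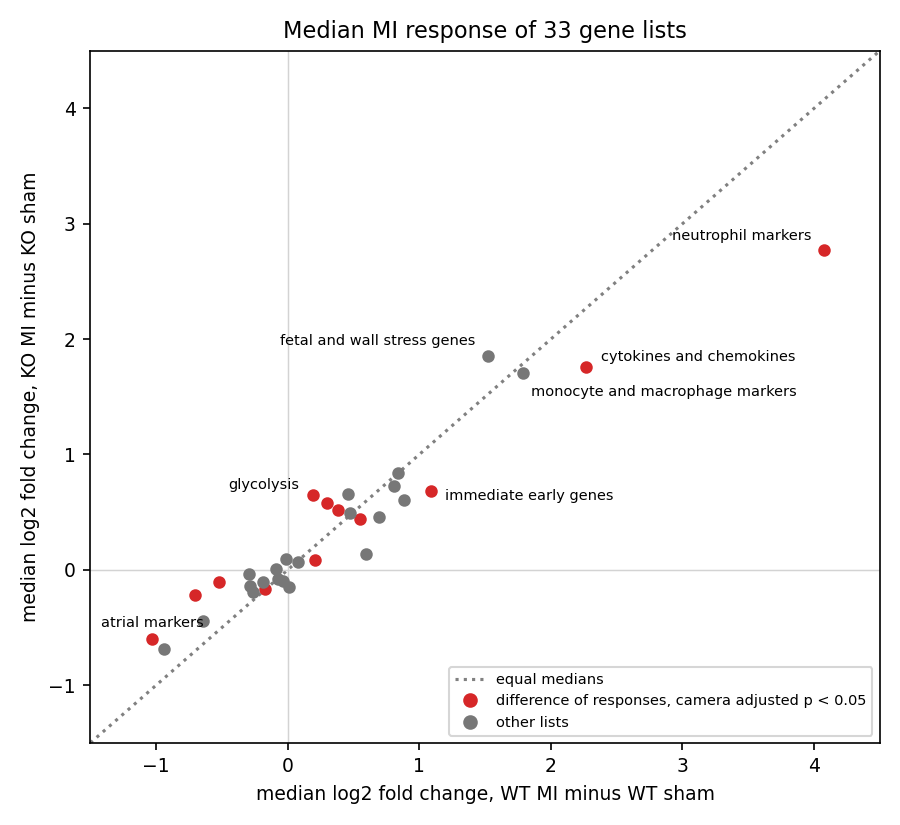
Each point is 1 of 33 gene lists, placed by the median log2 fold change of its members after MI in WT (horizontal axis) and in KO (vertical axis). The dotted line marks equal medians, and red marks the 12 lists whose responses differed by camera with its preset correlation, of which 0 passed with an estimated one. Neutrophil markers stood at 4.08 in WT and 2.77 in KO, while the median of their differences per gene was -0.75.

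The third comparison set KO against WT after sham surgery, and few genes differed. Acta1, the skeletal alpha-actin that the heart expresses in fetal life and under load, was 8.13-fold lower in KO sham (log2 fold change -3.02, SE 0.24, adjusted p = 0.00212). Nppa was 4.95-fold lower (log2 fold change -2.31, SE 0.25, adjusted p = 0.0154), the complement regulator Cd59a 3.77-fold lower (log2 fold change -1.91, SE 0.15, adjusted p = 0.00212) and Angptl7 3.41-fold lower (adjusted p = 0.0154). The small nucleolar RNA Snord14e was 6.43-fold higher (adjusted p = 0.0154). With Fbxo32 these made 6 genes, 1 higher and 5 lower, and 1017 genes had an unadjusted p under 0.05, where chance would give 997. Myh7, the slow beta-myosin heavy chain, was 3.46-fold higher in KO sham without passing (log2 fold change 1.79, SE 0.25, adjusted p = 0.076). Acta1 and Cd59a stayed past the threshold without any 1 array, but not with all probes tested (adjusted p = 0.159, range over alternatives 0.000219 to 0.159, and 0.155, range 0.000163 to 0.155), where Fbxo32 was the 1 call. With the 2 compared groups alone Fbxo32 and Acta1 kept their calls, and Cd59a (adjusted p = 0.0712), Nppa, Snord14e and Angptl7 did not. Nppa missed the threshold without KO sham replicate 1 (adjusted p = 0.13) or without 1 of the WT MI arrays (adjusted p = 0.056, range over alternatives 0.00212 to 0.306). Snord14e missed it without WT sham replicate 1 (0.0551), WT sham replicate 2 (0.146) or 1 of the WT MI arrays (0.0526, range over alternatives 0.000873 to 0.323). Angptl7 missed it without WT sham replicate 2 (0.114), KO sham replicate 1 (0.0963), KO sham replicate 2 (0.0501) or 1 of the WT MI arrays (0.0555, range over alternatives 0.00262 to 0.278). Myh7 passed without 1 of the KO MI arrays (adjusted p = 0.0122, range over alternatives 0.0122 to 0.361). The count of genes was 12 with an intensity trend in the prior, 13 with median centring, 34 (20 higher, 14 lower) without KO sham replicate 2, 13 without KO sham replicate 1, 11 without WT sham replicate 1 and 3 without WT MI replicate 1 or without WT MI replicate 2.

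Of the lists, 5 differed between KO sham and WT sham by camera with its preset correlation, and 0 with an estimated one. Atrial markers had all 7 members below 0 and a median of -1.24 (camera adjusted p = 2.15e-05, adjusted p = 0.798 with an estimated correlation), but Nppa alone passed among them (2 adjusted over the list alone). Their mean relative to WT sham was -0.56 and 0.56 in the WT sham arrays and -0.51 and -1.5 in the KO sham arrays, so the groups overlapped, and without KO sham replicate 2 the camera adjusted p was 0.183. That array was also the lowest sham array for the liver genes (-1.38 against -0.42 to 0.42) and for mesothelial markers (-0.35 against -0.12 to 0.12). WT sham replicate 2 was the highest sham array for these and for the atrial markers. Smooth muscle and pericyte markers had a median of -0.17 with 0 members past the test over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.000858, adjusted p = 0.798 with an estimated correlation), and Acta2, smooth muscle alpha-actin, had a log2 fold change of -1.65 (adjusted p = 0.302). Cell cycle genes lay higher (median 0.16, camera adjusted p = 0.000858, adjusted p = 0.798 with an estimated correlation). Oxidative phosphorylation genes (median -0.12, camera adjusted p = 0.00314) and proteasome subunits (median -0.10, camera adjusted p = 0.00423) lay lower, at an adjusted p = 0.878 and an adjusted p = 0.934 with an estimated correlation. In each of these last 3 lists 0 members passed, over all genes or adjusted over the list alone. Without KO sham replicate 1 the proteasome median was 0.06, and the smooth muscle (adjusted p = 0.0513) and oxidative phosphorylation (adjusted p = 0.663) shifts were lost. Without WT sham replicate 2 the oxidative phosphorylation (adjusted p = 0.0629) and proteasome (adjusted p = 0.0558) shifts were lost, and without KO sham replicate 2 that of cell cycle genes (adjusted p = 0.347). Cyclic loess also ended the oxidative phosphorylation (0.119) and proteasome (0.0573) shifts. The muscle ubiquitin ligases and FoxO genes, the family around Fbxo32, had a median of -0.02 and 0 of 19 members past the test (camera adjusted p = 0.529).

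The fourth comparison set KO against WT after infarction. Myh7 was 3.58-fold higher in KO MI (log2 fold change 1.84, SE 0.25, adjusted p = 0.0447), and the water channel Aqp8 (2.89-fold), the glycolytic regulator Pfkfb2 (2.21-fold), the synaptic scaffold Rapsn (2.06-fold), the epoxide hydrolase Ephx1 (2.04-fold) and Mtss1 (1.98-fold) were higher as well. Beside Fbxo32, Chil3 was 4.26-fold lower (log2 fold change -2.09, SE 0.24, adjusted p = 0.0248). The leukocyte genes Sla (2.45-fold), Jaml (2.32-fold) and Cd300lf (2.29-fold) were lower, as were the endothelial lipase Lipg (2.37-fold), the placental growth factor gene Pgf (2.28-fold) and the small nucleolar RNA Snora31 (2.02-fold). Aqp8 in WT MI and Lipg in KO MI read between 4.11 and 4.28, near the low end of the array, so their folds are uncertain. These made 14 genes, 6 higher and 8 lower, with 2337 at an unadjusted p under 0.05. Mtss1 and Sla lie on the chromosome of Fbxo32, 0.817 and 8.61 Mb from it in the RefSeq table. Fbxo32 was the gene that kept its call without each of the 8 arrays, and each of the other 13 lost it without at least 4 of the arrays, taken in turn. The count was 3 without WT sham replicate 1 or 2, 8 without KO sham replicate 1 or 2, 2 without WT MI replicate 2 and 3 without KO MI replicate 1 or 2. With all probes tested 0 genes passed, and with the 2 compared groups alone 2 did, both lower. More passed with an intensity trend (63, of which 40 higher), array weights (26, of which 14 higher) and low genes removed (23, of which 12 higher), so the side with more genes depended on the setting. Cyclic loess scaling gave 6 higher and 13 lower genes (31.6% higher, against 42.9%), so the share moved through the lower genes.

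All 21 neutrophil markers lay lower in KO MI than in WT MI, with a median of -0.77 (camera adjusted p = 9.03e-14). The adjusted p was 0.227 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 14 were lower. Retnlg passed without WT MI replicate 1 (adjusted p = 0.0129, range over alternatives 0.0129 to 0.492). With all arrays, Retnlg had a log2 fold change of -2.56 (SE 0.44, adjusted p = 0.0783), Mmp8, the neutrophil collagenase, -1.32 (SE 0.30, adjusted p = 0.168), and Il1r2 -1.26 (SE 0.25, adjusted p = 0.134). The mean of the list above WT sham was 3.12 and 3.54 in the WT MI arrays and 2.49 and 2.63 in the KO MI arrays, and without WT MI replicate 2 the median difference was -0.48. After sham surgery the list had a median of 0.00 (camera adjusted p = 0.732). Monocyte and macrophage markers had a median of -0.01 in KO MI against WT MI and did not pass (camera adjusted p = 0.109). Their median was 0.28 without WT MI replicate 1 and lay further below 0 without WT MI replicate 2. Over all genes 1 of their 23 members, Chil3, was lower, and adjusted over the list alone 4 were lower and 1 higher.

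**Figure D3:**
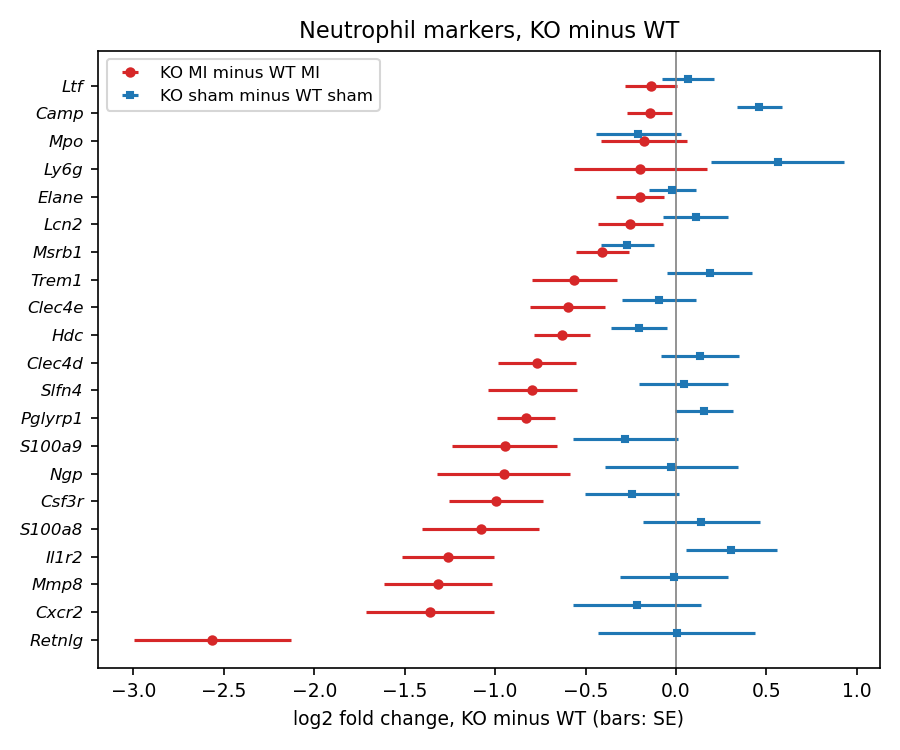
Points give the log2 fold change of KO against WT for 21 neutrophil markers after MI (red circles) and after sham surgery (blue squares), and bars give the standard error of the fit. All 21 lay below 0 after MI, with Retnlg lowest at -2.56.

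Cytokines and chemokines (median -0.17, camera adjusted p = 0.00145, 4 lower adjusted over the list alone), immediate early genes (median -0.23, camera adjusted p = 0.000155, 1 lower), endothelial markers (median -0.20, camera adjusted p = 0.00695, 0 lower) and lymphocyte markers (median -0.15, camera adjusted p = 0.0184, 0 lower) also lay lower in KO MI. With an estimated correlation their adjusted p values were 0.227, 0.49, 0.476 and 0.643. Higher in KO MI were fibroblast markers (10 of 10 above 0, median 0.21, camera adjusted p = 0.00145), cell cycle genes (median 0.23, camera adjusted p = 0.0292), extracellular matrix genes (median 0.14, camera adjusted p = 0.0328) and genes next to Fbxo32 (median 0.13, camera adjusted p = 0.0248). Their adjusted p values with an estimated correlation were 0.49, 0.729, 0.729 and 0.415. Over all genes 0 members of these lists passed, save Mtss1 among the neighbours of Fbxo32. Adjusted over the list alone, 1 fibroblast marker, 2 cell cycle genes, 4 extracellular matrix genes (1 further lower) and 2 neighbours were higher. Without WT MI replicate 2 the lymphocyte (adjusted p = 0.114), extracellular matrix (0.622) and cell cycle (0.15) shifts were lost. Without KO MI replicate 1 these were lost at 0.204, 0.578 and 0.302, and the neighbours of Fbxo32 at 0.109. Without WT MI replicate 1 the endothelial (0.235) and neighbour (0.0571) shifts were lost, and without KO MI replicate 2 the endothelial one (0.0838). The extracellular matrix shift was also lost without any 1 sham array (0.056 or 0.057). The 4 higher and 5 lower lists became 2 and 6 with cyclic loess, which ended the lymphocyte (0.0883), extracellular matrix (0.2) and neighbour (0.0745) shifts. They became 2 and 8 with low genes removed, which ended the extracellular matrix (0.189) and cell cycle (0.0898) shifts, 2 and 10 without WT MI replicate 2, and 1 and 7 without KO MI replicate 1. Among collagens Col3a1 had a log2 fold change of 0.83 (SE 0.14, adjusted p = 0.0783) and Col1a1 of 0.73 (SE 0.15, adjusted p = 0.152). Among matrix proteases and inhibitors, Mmp9 had a log2 fold change of -0.87 (SE 0.19, adjusted p = 0.161) and Plaur of -0.78 (SE 0.12, adjusted p = 0.0663). Adamts5 went the other way, at 6.282 and 6.669 in WT MI and 7.349 and 7.205 in KO MI. Of 25 members 12 lay above and 13 below 0 (2 higher and 6 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.196).

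Averaged over both conditions, 4 KO arrays against 4 WT arrays, 5 genes were higher and 6 lower in KO. Myh7 was 3.52-fold higher (log2 fold change 1.82, SE 0.17, adjusted p = 0.00529) and kept its call without any 1 array, but not with all probes tested (adjusted p = 0.154, range over alternatives 0.00083 to 0.154), where Fbxo32 was the 1 call. Olfml2b (2.10-fold), Mtss1 (1.73-fold), the copper carrier ceruloplasmin Cp (1.71-fold) and the laminin subunit Lama5 (1.63-fold) were higher, each at an adjusted p of 0.0436. Fbxo32 (10.7-fold), the myosin light chain Myl1 (2.13-fold), Klk1b11 (1.91-fold), the Z-disc protein genes Pdlim3 (1.85-fold) and Pdlim7 (1.61-fold), and Pcp4l1 (1.59-fold) were lower. Klk1b11 read between 3.13 and 3.61 in the KO arrays, near the low end. Acta1 had a log2 fold change of -2.08 (SE 0.33, adjusted p = 0.108) and passed without WT MI replicate 2 (adjusted p = 0.0402, range over alternatives 0.0326 to 0.585). The KO effects in sham and in MI hearts, which share no array, correlated across genes at r = 0.03, and 1 gene, Fbxo32, passed in both. Of 6 lists that shifted, cell cycle genes (median 0.20, camera adjusted p = 9.69e-05) and genes next to Fbxo32 (median 0.06, camera adjusted p = 0.0227) lay higher, and neutrophil (median -0.35, camera adjusted p = 1.06e-06), endothelial (median -0.13, 0.00352), atrial (median -0.68, 0.0114) and immediate early genes (median -0.12, 0.0166) lower. With an estimated correlation 0 of them passed, at adjusted p values between 0.555 and 0.754. Over all genes 0 of their members passed except Mtss1, and adjusted over the list alone Mtss1 was again the 1 that did. The atrial shift was lost without WT sham replicate 2 (adjusted p = 0.177) or KO sham replicate 2 (adjusted p = 0.229), and the endothelial one without WT MI replicate 1 (adjusted p = 0.0725). Immediate early genes lost theirs without WT sham replicate 2 (0.0935), WT MI replicate 1 (0.0725), WT MI replicate 2 (0.107) or KO MI replicate 1 (0.336), and the neighbours of Fbxo32 without WT MI replicate 1 (0.0725) or KO MI replicate 1 (0.0986) and with cyclic loess (0.0527). The count of 11 genes was 2 or 3 without either WT sham array, either KO sham array, WT MI replicate 1 or either KO MI array, and centring on array medians gave 3 genes, with 33.3% on the higher side against 45.5%.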

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

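The leave-out tests of the neutrophil and atrial markers and the test of the genes near Fbxo32 were chosen only after the result was seen, as was the choice to count only splits with equal numbers of sham arrays on both sides. The other tests were set in advance. The MI response of 12 lists differed between KO and WT by camera with its preset correlation, and with an estimated correlation 0 did. The median differences (KO minus WT) below 0 were -0.7536 for neutrophil markers, -0.2534 for lymphocyte markers, -0.3314 for cytokines and chemokines, -0.311 for immediate early genes and -0.1234 for cell death. Those above 0 were 0.1895 for extracellular matrix, 0.3596 for fibroblast markers, 0.3457 for smooth muscle and pericyte markers, 0.148 for cardiomyocyte contractile and calcium genes, 0.2329 for glycolysis, 0.1512 for proteasome and 1.061 for atrial markers. Their adjusted p values ran from 1.03e-10 for neutrophil markers to 0.0183 for glycolysis with the preset correlation, and from 0.226 to 0.674 with an estimated one. Atrial, smooth muscle and proteasome genes differed between KO and WT in sham (medians -1.24, -0.17 and -0.10) and not in MI. There the medians were -0.12, 0.07 and 0.05 (camera adjusted p = 0.868, 0.501 and 0.501), so these differences of response came mainly from the sham arrays. Leaving out 1 array ended the difference of 7 of the 12, those of lymphocyte, extracellular matrix, cardiomyocyte, glycolysis, proteasome, cell death and atrial genes. Of the 12, with 7 above and 5 below 0, cyclic loess kept 7 and removal of low genes kept 8, and both called 3 lists above and 7 below 0 in all, so the side with more lists depended on the setting. Both ended the differences of extracellular matrix, cardiomyocyte, glycolysis and proteasome genes, and cyclic loess also that of lymphocyte markers. Probes that the annotation does not list stood outside the comparisons, and 1147 of them changed in WT MI and 996 in KO MI, against 0 between KO and WT in sham or in MI.

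Neutrophil markers lay lower in KO MI than in WT MI, with a median of -0.77 over 21 genes. A response scaled down for all genes alike, as with less injured tissue in the sample, would give other genes with the same mean MI response a like KO effect. Of 10000 lists of genes matched on that response 0 had a median as low (median of the lists -0.22, lowest -0.62). The one-sided p from these matched draws was 1e-04, the smallest these lists can give, with draws that treat genes as independent. It met the bound set in advance against that explanation, a one-sided share under 0.05. The bound does not settle the question, because the list holds some of the largest rises, for which genes of like response are few. Over all genes the KO response had a slope of 0.81 on the WT response (total least squares), so a smaller response in KO was not limited to this list. Leaving out 1 of the MI arrays brought the median at most to -0.4788, without WT MI replicate 2. The list mean above WT sham was already higher in both WT MI arrays (3.12 and 3.54) than in both KO MI arrays (2.49 and 2.63). Leaving out 1 array could therefore not turn the direction of that mean, and the leave-out test adds only the size that remained. Less injured tissue, fewer neutrophils, a lower level per cell, or differences between hearts and the place sampled may each account for the lower median. With 2 arrays per group and a camera adjusted p of 0.227 at an estimated correlation none was tested further.

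Atrial markers lay lower in KO sham than in WT sham, and a sample with less atrial tissue may account for it. The bound set in advance said that this explanation fails if any of Sln, Myl4 and Myl7 is not lower by more than 2 SE, and all 3 met it, with the smallest fall at -1.11 SE. The values were -0.29 (SE 0.27), -1.31 (SE 0.72) and -1.24 (SE 0.98), all below 0 and none apart from the bound by more than its SE, so after the result was seen the bound was judged too weak to exclude the explanation. Leaving out 1 sham array brought the median to -0.1481 without WT sham replicate 2 and ended the call without KO sham replicate 2. The call thus rests on KO sham replicate 2, and the size of the shift also on WT sham replicate 2. The mean of the list was 0.56 in WT sham replicate 2, against -0.56 in WT sham replicate 1 and -0.51 in KO sham replicate 1. KO sham replicate 2 was also the lowest sham array for liver genes (-1.38 against -0.42, 0.42 and 0.08) and mesothelial markers (-0.35 against -0.12, 0.12 and -0.09). WT sham replicate 2 was the highest for both (0.42 and 0.12). Tissue taken along differently into either sample stays open, as does the KO itself, which was not tested.

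Mtss1, 0.817 Mb from Fbxo32, was higher in KO and Sla, 8.61 Mb from it, lower in KO MI, and DNA of another strain kept beside the deletion could change genes nearby. Of 226 genes within 20 Mb, 10.2% had an unadjusted p under 0.05 in the averaged KO effect, against 7.24% of the other genes (one-sided Fisher's exact p = 0.0643). The shares were 15.5 against 11.7% in MI (one-sided Fisher's exact p = 0.0521). They were 4.42 against 5.1% in sham (one-sided Fisher's exact p = 0.72), where such DNA would be present too. In sham 1017 of all genes had an unadjusted limma p under 0.05, where chance would give 997, so the sham share could show little. Nearer Fbxo32, Mtss1, Washc5, Tbc1d31, Atad2, Tmem65, Tatdn1 and a Riken-named gene, all within 1.16 Mb, had an averaged unadjusted limma p under 0.05. Each was higher in KO in sham and in MI, but Mtss1 alone passed adjusted. The other genes measured in that range were Zhx1, Derl1, Sqle, Fam83a, Slc22a22, Wdyhv1, Zhx2, Klhl38, Trmt12, Anxa13, Fam91a1, Rnf139, Ndufb9 and Fer1l6. None of these reached that p. The range was chosen after the values were seen. Over 20 Mb the averaged share was higher without passing and the one in sham was not higher, so the test leaves this open. The strain is not given in the sources used here.

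The averaged KO effect uses condition as a term, so arrays can be exchanged only within a condition. The 18 splits of the 8 arrays with 2 sham and 2 MI arrays on each side are too few for a share under 0.05. Of them 1, the real one, gave as many as 11 genes, and the highest of the others gave 0.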

How the results depend on the processing

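The removal of KO sham replicate 1 and WT MI replicate 2 together was chosen only after the result was seen. The adjusted p of named genes with all probes tested was also added then. The other alternatives were planned. Fbxo32 in KO sham and averaged kept its direction and call under every alternative run. Fbxo32 in KO MI and Acta1 in KO sham did so under all but all probes (adjusted p = 0.0523 and 0.159), where their folds are the ones of the test by gene and the prior and the adjustment differ, and the neutrophil markers in KO MI (median -0.87 to -0.48) under all but camera with an estimated correlation and fry. For the counts and directions that follow the cause was not tested, except that a 2-fold minimum, all probes, fewer groups or fewer arrays change a count by construction. Genes near the array's floor have compressed folds, which limits what can be called there.

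A 2-fold minimum left 1670 genes in WT MI, 1026 in KO MI and 4 for the averaged KO effect. An intensity trend gave 12 genes for KO in sham, 63 for KO in MI and 4 for the difference of the responses. Array weights gave 26 and removal of low genes 23 for KO in MI. The 2 compared groups alone gave 3 (KO in sham) and 2 (KO in MI). Median centring gave 13 (KO in sham) and 3 (averaged), and cyclic loess 1 (difference) and 3 lists (KO in sham). All probes gave 1 (KO in sham), 0 (KO in MI, by limma, where the test by gene had 2337 genes at an unadjusted p under 0.05) and 1 (averaged). Without genes within 20 Mb of Fbxo32, 8 of 14 remained for KO in MI. Of the 14, only Mtss1 and Sla were removed, so the others that dropped out did so through the changed prior and adjustment. Camera with an estimated correlation called 1 list in WT MI, 2 in KO MI and 0 in each KO contrast and the difference. Fry called 20 lists in WT MI and 16 in KO MI. For the other contrasts fry called 0 (KO in sham), 2 (KO in MI), 1 (difference) and 0 (averaged). The 2 for KO in MI were cytokines and chemokines, lower (fry adjusted p = 0.0168), and genes next to Fbxo32, higher (fry adjusted p = 0.0358). Without KO sham replicate 1 and WT MI replicate 2 together, 3 genes differed for KO in MI and 4 for the averaged effect.

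Leaving out 1 array at a time gave 3457 to 6483 genes in WT MI, 2246 to 4099 in KO MI, 3 to 34 for KO in sham, 2 to 11 for KO in MI, 0 to 3 for the difference and 2 to 9 for the averaged effect. It gave 2 to 8 lists for KO in sham and 6 to 15 for the difference. With the replicate number as a block (replicate block), 5248 genes changed in WT MI, 3811 in KO MI, 7 for KO in sham, 5 for KO in MI, 0 for the difference and 3 for the averaged effect. Deviations of same-numbered arrays correlated across genes between -0.187 and 0.156, the highest for WT MI with KO MI. They thus showed no strong shared signal, but a weaker pairing of the arrays by number is not excluded.

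The direction turned for the proteasome in KO sham without KO sham replicate 1 (0.06283) and with both arrays out (0.06283), and in the difference (-0.01828 and -0.02175 in the same order). It turned for extracellular matrix in the difference with both out (0.02073). Among results that had not passed, it turned for ubiquitin ligases in KO sham (0.08006 without KO sham replicate 1 and with both out), for monocyte and macrophage markers in KO MI without WT MI replicate 1 (0.2762), and for neutrophil markers in KO sham with low genes removed (median 0.003575, by the test alone). It turned for Sln without KO sham replicate 2 (0.1722) and for Myl7 without WT sham replicate 2 (0.1149) or KO sham replicate 2 (0.4151). In WT MI it turned for endothelial markers with cyclic loess (0.1003) and both out (0.03751), and for autophagy with low genes removed (-0.0135), cyclic loess (0.03934) and without WT sham replicate 1 (-0.007335). It turned there for mesothelial markers without WT MI replicate 1 (-0.04885). For adipose markers it turned with low genes removed (-0.107), the 2 groups alone (-0.07134), without WT sham replicate 1 (-0.1463), KO sham replicate 1 (-0.07134), KO sham replicate 2 (-0.07134) or WT MI replicate 2 (-0.1554), and with both out (-0.1554). For these results the values left by single arrays ended, at the other side, at -0.0228 (without WT MI replicate 2) and -0.00364 (without WT sham replicate 2) for autophagy, 0.1475 for adipose markers (without WT MI replicate 1), and -0.3354 (without WT MI replicate 2) and 0.08329 (without WT sham replicate 2) for mesothelial markers, all in WT MI. For KO in sham they ended at -0.1415 for ubiquitin ligases and -0.2705 for proteasome (without KO sham replicate 2), and -0.7581 for Sln and -2.889 for Myl7 (without KO sham replicate 1). For KO in MI monocyte and macrophage markers ended at -0.3283 (without WT MI replicate 2), and in the difference the proteasome ended at 0.3175 (without KO sham replicate 2). Where a median kept its sign, the direction is that of the test.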

Other observations

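The list of liver genes was written after the values of Alb were seen and before those of its members. In WT MI 7 of 15 liver genes fell (median -0.97), against 0 in KO MI (median -0.61, 13 below 0). In KO sham against WT sham 0 passed, all 15 lay below 0 and the median was -0.46. The mean of the list relative to WT sham was -0.42 and 0.42 in the WT sham arrays, 0.08 and -1.38 in the KO sham arrays and between -1.34 and -1.04 in the MI arrays. Cyp2e1, a liver cytochrome, read 5.93 and 7.43 in WT sham, 6.67 and 4.02 in KO sham and 3.83 to 4.15 after MI. No source of these transcripts was tested.

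Lists that did not shift in WT MI were resident macrophage markers (median -0.04, 1 rose and 2 fell of 10, camera adjusted p = 0.595), endothelial markers (0.01, 2 and 2 of 16, 0.62), muscle ubiquitin ligases and FoxO genes (-0.29, 3 and 6 of 19, 0.0885), autophagy (-0.01, 1 and 1 of 17, 0.882), cell cycle (0.08, 3 and 2 of 22, 0.741), adipose (-0.07, 0 of 8, 0.841), mesothelial (-0.09, 0 of 7, 0.589) and erythrocyte markers (0.60, 0 of 3, 0.157), and genes next to Fbxo32 (-0.28, 4 and 9 of 21, 0.108). Adjusted over the list alone, the rises and falls of these lists matched those over all genes save 7 falls of ubiquitin ligases and 2 rises of cell cycle genes. Erythrocyte markers passed without WT MI replicate 2 (adjusted p = 0.0289). The signs of median, mean and test differed in lists that did not pass. These were endothelial and adipose markers in WT MI, genes next to Fbxo32 in the KO response, and resident macrophage, erythrocyte, immediate early, unfolded protein and calcineurin genes for KO in sham. They also were fetal, interferon-stimulated, hypoxia and mesothelial genes for KO in MI, interferon-stimulated and unfolded protein genes in the difference, and monocyte and hypoxia genes in the averaged effect. Xist, the transcript of the inactive X chromosome, read between 2.78 and 3.17 in all 8 arrays, and the Y-linked Uty read 5.44 in WT MI replicate 2 against 6.61 to 6.95 in the other MI arrays.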
